A study of Gasterosteus aculeatus with 242 samples.

How the data were processed

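Messenger RNA was measured in brain tissue of 242 juvenile threespine sticklebacks by 3′ tag sequencing, which reads a stretch near the poly(A) tail, so that a count stands for a transcript end and does not grow with gene length. Per the labels' protocols, the left or the right part of each brain was kept for RNA, RNA was extracted on a 96-well robot kit, and libraries were sequenced on 6 lanes. The deposited table holds whole-number counts per Ensembl gene for each library and lane, in 1452 columns. The submitters' processing notes name FastQC 0.11.8, STAR 2.2.3a and HTSeq 0.9.1, with no order or settings. The genome build, the annotation release, any duplicate removal and the strand setting of the counting are not given in the sources used here. Reads from near-identical gene copies, from overlapping genes and from antisense pairs may therefore have been split or lost by the authors' counting, and counts of such genes are uncertain.

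Every count column was matched to a fish by the library name in the labels, and no column was left without a fish. The 6 lanes of a library were summed and treated as 1 replicate. Lane counts of a library differed by little more than sampling noise (chi-square per degree of freedom at most 1.11), whereas the most alike pair of libraries among 7153 pairs of the same group had a chi-square of 2.62 per degree of freedom, so no library was taken for a copy of another. Of 22456 gene identifiers, 20626 had at least 1 count. The files do not pair identifiers with gene symbols, and none of the 22456 identifiers matched the reference table of 52177 genes that was at hand. Genes are therefore given by identifier only, at most 2 that rose and 2 that fell per comparison. No chromosome could be assigned. The 23 gene lists fixed beforehand (immediate early genes, hormone, neuropeptide, glial, immune, circadian and other lists) need symbols, so none of them was tested and no gene list test was run.

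Groups were taken from the labels: rearing (Day 10, raised by the father; Day 0, hand-reared), exposure (baseline or open field), sex and hemisphere. The leading number of a fish code was read as its family. The labels describe each open-field fish as matched to a full sibling, and matched codes share that number. This reading was checked in the counts. Within rearing, exposure and sex, the median intraclass correlation of a gene over these numbers was 0.065, against at most -0.00068 in 100 shuffles of the numbers within a rearing group. The leading digit of a library name was read as its plate. Each of the 3 plates held fish of all 16 families. The design is described as half-sib, and the labels used here do not say which families share a parent, so shared parents were not modelled. Fish are separate animals. Rearing was applied to whole families, so the family is the replicate for rearing.

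Depth was similar across groups. The median library held 1005960.5 counts and all but 1 lay between 706544 and 1529047. A single hand-reared open-field library, fish 25E6, held 2055 counts. It was kept in the tests, where its weight is small, and left out of all values per fish and per family and of the gene groups, for which libraries under 500000 counts were not used. An alternative left it out of the tests too.

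Genes were kept with edgeR's filterByExpr over the 4 groups of rearing and exposure (minimum count 10), which left 7682. The main test was edgeR's quasi-likelihood F-test (version 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, a trended dispersion and Benjamini-Hochberg adjustment. A gene is called at an adjusted p under 0.05. Exposure, sex and hemisphere were tested over all 242 fish with family as a block and the other terms plus plate as covariates. Exposure was also nested in rearing, and sex-by-rearing and sex-by-exposure terms were fitted in the same way. Rearing was tested on counts summed over the fish of a family, 8 families against 8, for all fish, for baseline fish and for open-field fish. These sums were tested with no term for sex, hemisphere or plate. Plates themselves differed widely, with 3843 genes called between plates 2 and 1 and 4276 between plates 3 and 1. The rearing-by-exposure term was tested on 32 sums of family and exposure with family as a block. Log2 fold changes come from these fits. Their standard error is the log2 fold change divided by the square root of F. Values per fish are counts per 1000000 counts (CPM) after TMM scaling, computed here, with the standard deviation over fish. Single values per family were compared with exact permutation tests, two-sided, over all 12870 assignments of 16 families to 8 and 8.

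The edgeR comparisons and the alternatives were fixed before the data were examined. Permutation tests on values per family and the gene groups were not among them. The alternatives were DESeq2 1.42.0 with its size factors, limma-voom 3.58.1, no filter on low counts, no plate term, no family block, sibling numbers as a block, each sex or hemisphere alone, sums of family and exposure, each rearing group fitted alone, the 2055-count library left out, each family left out, the share of males as a covariate, and for rearing the single fish as the unit, with and without family as a random effect. Fits of single plates were planned for exposure and added for sex, hemisphere and rearing after seeing the data. The fixed rule for named genes took the 8 largest fold changes up and down per comparison among called genes with a mean of at least 5 CPM and a symbol, plus members of the gene lists and, without calls, the 5 genes with the smallest p. With no symbols it names none, so the first 2 identifiers up and down by that ranking are given instead, a change made after the data were seen.

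Gene groups were average-linkage clusters of at least 20 genes on the correlations of log2 CPM (prior count 2) left after family, sex, hemisphere, plate and exposure, joined down to a mean correlation of 0.35. A group's score in a fish is the mean of its standardised genes, and in a family the mean over fish adjusted for the other terms. Counts of called genes were set against other splits of the samples into groups of the same sizes, 100 for family sums and 21 for slower fits, the real split included.

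The tests were run on simulated counts drawn for the 7682 genes from the real means, library sizes and spread, with 200 genes changed. Apart from the planted group below, genes were drawn independently of each other, in a single run per comparison. For exposure edgeR called 65 of 67 genes changed 1.3-fold and all 67 changed 1.5-fold, with 4.35% of calls false. For rearing on family sums it called 48 of 67, 55 of 67 and 63 of 66 genes changed 1.3-fold, 1.5-fold and 2-fold, with 3.49% of calls false, and for rearing by exposure 42, 60 and 65 with 4.02% false. DESeq2 on the family sums called 52, 58 and 63, with 11.7% of calls false, and 9.63% at baseline. A planted group of 60 genes sharing a random value per fish was returned by the search for gene groups with 57 of its members in 1 group.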

Results

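The series asked how care by the father shapes the brain's expression in offspring, and how it bears on the response to a new, threatening place. Threespine sticklebacks (Gasterosteus aculeatus) are small fish in which the father alone tends the nest and fry. Offspring of wild-caught fathers were either left with the father (Day 10 in the labels) or taken from him and raised by hand (Day 0). At 6 to 8 months of age, before maturity, fish of both kinds were placed alone in a pool, the open field, for 10 minutes, after which a model of a sculpin, a predatory fish, was moved through it. Their brains were taken 60 minutes after that simulated attack. The labels describe each as matched to a full sibling from a home tank, which gave the baseline. The sibling's brain was taken within 30 minutes of its own. The open-field group thus differs from baseline by the pool, the model and the hour that followed, all at once.

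The 242 fish came from 16 families, 8 per rearing group, with 12 to 18 fish each. Of these fish, 12 had no partner of the other exposure with the same family and fish number. There were 64 baseline and 60 open-field fish that were hand-reared, and 57 baseline and 61 open-field fish that were father-reared. The sexes were told apart by the submitters with a DNA marker, and the left or the right side of each brain was used. Hand-reared baseline fish were 25 females and 39 males (33 left and 31 right sides), and hand-reared open-field fish were 32 females and 28 males (31 left, 29 right). Father-reared baseline fish were 26 females and 31 males (25 left, 32 right), and father-reared open-field fish were 35 females and 26 males (30 left, 31 right). Median library totals were 1021248.5 counts in hand-reared baseline fish, 1003147 in hand-reared open-field fish, 991679 in father-reared baseline fish and 1031716 in father-reared open-field fish. At this depth a median of 13609 genes had at least 1 count in a library, and 7682 were counted often enough to be tested. A single hand-reared open-field library, of fish 25E6, was too shallow for values per fish, so means and SDs per fish cover all fish of a group but that one. Identical molecules cannot be set apart in the deposited counts, and whether duplicates were removed before is not given.

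Exposure to the open field raised a small set of brain genes and lowered very few. The largest rise was in ENSGACG00000010476, from 28.4 ± 14.4 CPM in baseline fish (SD, n = 64 hand-reared and 57 father-reared) to 79.3 ± 23.3 CPM in open-field fish (SD, n = 59 and 61), a 2.80-fold increase (log2 fold change 1.49, SE 0.07, adjusted p = 1.9e-53). ENSGACG00000016157 rose from 96.3 ± 42.7 to 217.2 ± 67.5 CPM (log2 fold change 1.18, SE 0.07, adjusted p = 1.6e-42). Both were higher in open-field fish in 16 of 16 families, and a single baseline fish lay above the open-field median of ENSGACG00000010476. In all, 43 genes rose and 5 fell by edgeR's quasi-likelihood test among 7682. The median rise was 0.32 on the log2 scale, and 13 calls exceeded 1.5-fold. Of the 43 genes that rose, 25 did so in every family and none in fewer than 11 families.

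The 5 genes that fell changed little. ENSGACG00000010806 went from 16.7 ± 5.38 CPM in baseline fish to 13.9 ± 4.33 CPM in open-field fish (log2 fold change -0.28, SE 0.06, adjusted p = 7.8e-04), lower in 14 of 16 families. ENSGACG00000011606 went from 18.4 ± 7.25 to 15.2 ± 6.44 CPM (log2 fold change -0.26, SE 0.07, adjusted p = 0.041), also lower in 14 of 16 families. The first call was lost in 7 of 15 alternative analyses and the second in 9 of 15, many of them on part of the fish, with log2 fold changes from -0.35 to -0.20 and from -0.35 to -0.18. Fish of the exposure groups overlapped widely for both. Within single plates, as read from the library names, 24, 22 and 21 genes were called. Of the 48 genes called over all fish, 46 kept their direction in all 3 plates. All 48 also had the same direction in males and in females, though they were chosen over these same fish.

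**Figure D1:**
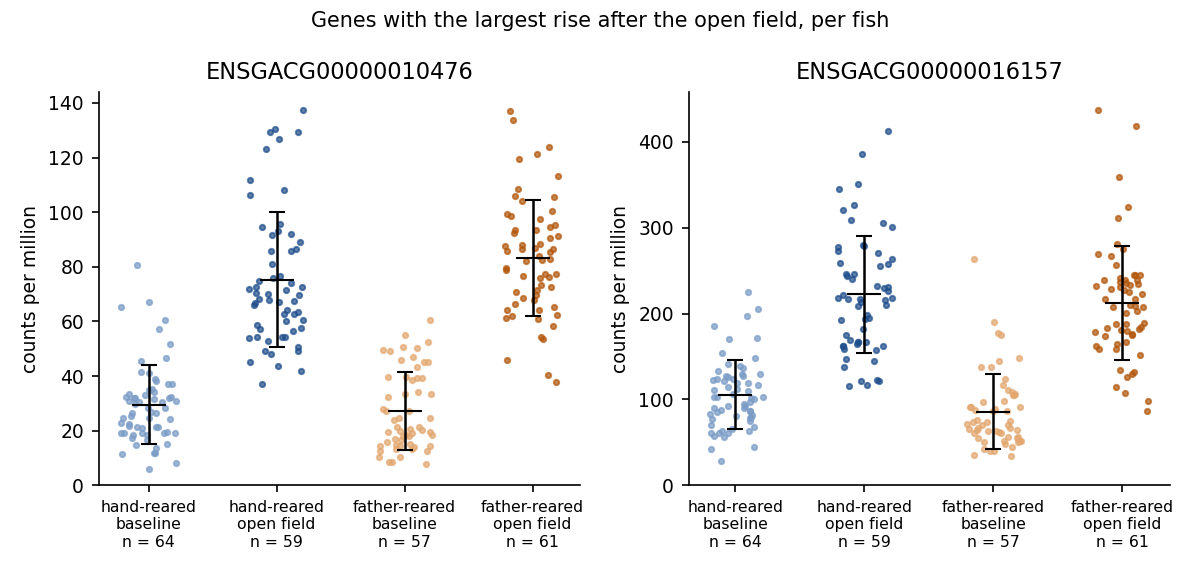
CPM (vertical axis, linear, starting at 0) of the genes with the largest rise, one point per fish, in the 4 groups of rearing and exposure; horizontal bars are means and vertical bars standard deviations. In both rearing groups the open-field mean of ENSGACG00000010476 (75.3 and 83.3 CPM) lies far above the baseline mean (29.6 and 27.2 CPM).

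The response to the open field was present in both rearing groups and in largely the same genes. ENSGACG00000010476 rose by 1.35 (SE 0.09) on the log2 scale in hand-reared and by 1.63 (SE 0.10) in father-reared fish, and ENSGACG00000016157 by 1.07 (SE 0.09) and 1.299 (SE 0.09). In hand-reared fish 25 genes rose and 0 fell. In father-reared fish 28 rose and 2 fell. The lists shared 23 genes, where independent lists would share 0.098. The 48 genes called over all fish had the same direction in both groups, and their log2 fold changes correlated across genes with a Pearson r of 0.97, against 0.344 over all 7682 genes (genes are not independent replicates, and the 48 were chosen for their response). For the 0 genes that fell in hand-reared fish, 340 genes of either direction had an unadjusted p under 0.05, and DESeq2 also called 28 genes that rose and 0 that fell. Without the filter on low counts 30 rose and 3 fell, among 20626 genes.

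Whether rearing changed the response was tested as the difference itself, with families as replicates. No gene passed: edgeR called 0 of 7682 genes for rearing by exposure, with 3.02% of them at an unadjusted p under 0.05, and DESeq2 called 0, with 72 genes at an unadjusted p under 0.05. Over the 43 genes that rose, the mean response of a family was 0.488 ± 0.067 log2 units in father-reared families (SD, n = 8) and 0.424 ± 0.087 in hand-reared families (SD, n = 8). The difference of 0.064 (SE 0.039) was within the spread of families (exact permutation test, two-sided, p = 0.12). Baseline levels of these genes also did not differ beyond the spread of families, at 5.14 ± 0.11 and 5.19 ± 0.063 log2 CPM (exact permutation p = 0.23). The response difference was 0.128 (exact permutation p = 0.062) with the shallow library of fish 25E6 included.

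**Figure D2:**
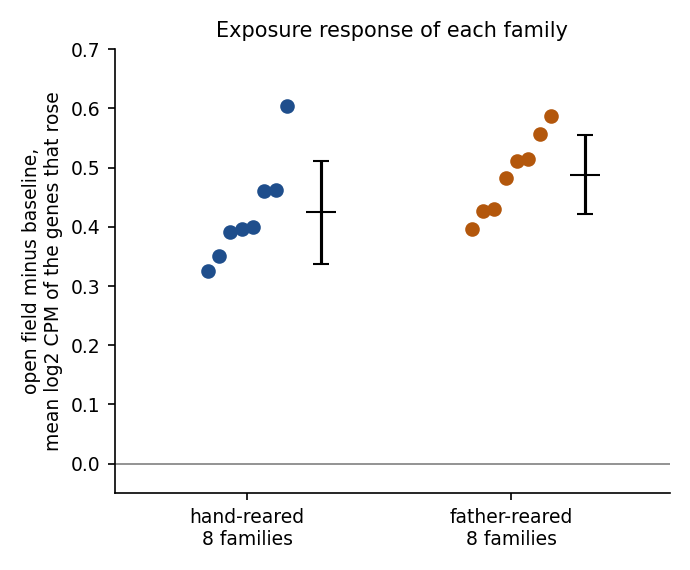
Open-field minus baseline difference in mean log2 CPM over the 43 genes that rose (vertical axis), one point per family, for 8 hand-reared and 8 father-reared families; bars beside the points are the mean and standard deviation over families. All families lie between 0.326 and 0.605, and the rearing groups overlap.

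With families as the replicates, edgeR called no gene between father-reared and hand-reared fish, whereas DESeq2 called 20. The edgeR test on family sums, which held no term for sex or plate, called 0 of 7682 genes over all fish, with 549 at an unadjusted p under 0.05. It called 0 in baseline fish, with 515 at an unadjusted p under 0.05, and 0 in open-field fish, with 461. With the share of males as a covariate edgeR also called 0 over all fish, with 445 at an unadjusted p under 0.05. The median standard error of a rearing difference was 0.07 on the log2 scale, and for 93.5% of genes the 95% interval (normal, from the SE) stayed within 1.5-fold of no change. Differences larger than that were therefore excluded gene by gene for most of the tested genes, and small ones were not. In each plate alone the family sums gave 0 calls (edgeR, with 595, 509 and 338 genes at an unadjusted p under 0.05).

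The count of rearing genes depended on the tool and on how siblings entered the test. On the same family sums DESeq2 called 19 genes higher and 1 lower in father-reared fish, 25 and 1 at baseline, and 13 and 0 after the open field. In simulated family sums over all fish 11.7% of DESeq2 calls were false, against 3.49% by edgeR. The simulated genes were drawn independently of each other in a single run, so these rates may not hold for real genes that vary together. With single fish as the unit and family as a random effect, limma called 2.33% of the 7682 genes higher and 0.208% lower, 83 and 6 genes at baseline, and 77 and 5 after the open field. With single fish as independent replicates, edgeR called 530 higher and 287 lower. Of the 20 genes DESeq2 called over all fish, 16 belonged to a group of genes, 1.84% of those tested, that rise and fall together from fish to fish, as did 61.03% of those limma called.

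Of exposure, sex and hemisphere, sex had the called genes with the largest fold changes. ENSGACG00000006281 averaged 142.8 ± 29.2 CPM in males and 6.48 ± 2.78 CPM in females (SD, over all fish of the sex with usable depth), a log2 fold change of 4.38 (SE 0.05, adjusted p = 1.4e-174). The sexes did not overlap: the highest female reached 15.5 CPM and the lowest male 59.03 CPM, so each fish with usable depth matched its sex label by this gene. ENSGACG00000003306 averaged 11.7 ± 9.81 CPM in males and 0.146 ± 0.389 CPM in females (log2 fold change 5.32, SE 0.15, adjusted p = 5.2e-92), and limma-voom gave 3.94, so the size of this fold depends on the tool. Among genes higher in females, ENSGACG00000006516 averaged 37.8 ± 17.8 CPM in females and 14.7 ± 9.62 CPM in males (log2 fold change -1.23, SE 0.09, adjusted p = 4.3e-32). ENSGACG00000005982 averaged 8.97 ± 5.78 and 4.104 ± 3.30 CPM (log2 fold change -1.19, SE 0.12, adjusted p = 6.9e-18). All 4 genes kept their direction in 16 of 16 families.

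Over all genes, 653 were higher in males and 396 higher in females by edgeR's test. The directions differed in size. Most male-higher calls were small, with 465 of 653 under 0.3 on the log2 scale, and the median was 0.18. Female-higher calls fell into a group near 0 and a group near -1: 33.6% of the 396 lay between -1.1 and -0.9, and 28 genes lay between -0.7 and -0.5. Of the male-higher calls 7 lay in the mirror range from 0.9 to 1.1. Single plates gave 391, 507 and 339 calls, of which 66.5%, 52.1% and 70.21% were higher in females. Of the 1049 genes called over all fish, 1028 kept their direction in each plate, though they were chosen over these same fish.

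**Figure D3:**
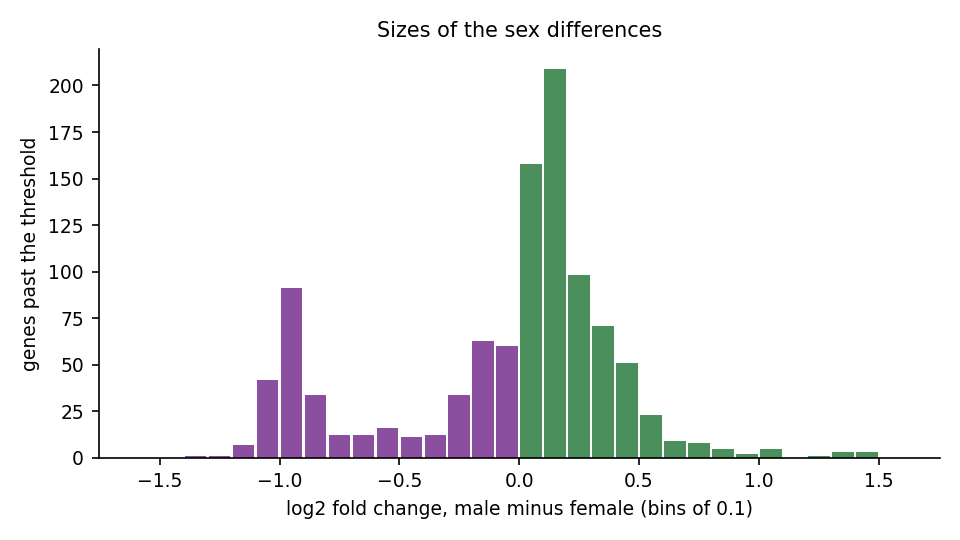
Number of genes past the threshold (vertical axis) by log2 fold change between males and females in bins of 0.1 (horizontal axis); bars left of 0 are genes higher in females, bars right of 0 genes higher in males. Calls higher in females show a second peak near -1, and 7 calls beyond the plotted range of -1.6 to 1.6 are not drawn.

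The sex difference was not shown to depend on rearing or exposure. The sex-by-rearing term gave 0 calls (edgeR, 327 genes at an unadjusted p under 0.05, DESeq2 0), and the sex-by-exposure term gave 0 calls (edgeR, 387 genes at an unadjusted p under 0.05, DESeq2 0). Over the 43 genes that rose in the open field, the median rise was 0.30 log2 units in males and 0.37 in females.

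Few genes were called between the left and right brain sides, with wide spread between fish. ENSGACG00000017329 averaged 14.5 ± 16.9 CPM in left sides and 6.14 ± 12 CPM in right sides (SD, over all fish of the side with usable depth), a log2 fold change of -1.43 (SE 0.27, adjusted p = 0.0012), and was higher on the left in 13 of 16 families. ENSGACG00000006256 averaged 7.66 ± 9.90 and 3.57 ± 6.67 CPM (log2 fold change -1.17, SE 0.23, adjusted p = 0.0012). On the right, ENSGACG00000005997 was higher at 119.6 ± 118.6 against 73.9 ± 71.2 CPM (log2 fold change 0.64, SE 0.16, adjusted p = 0.045), and ENSGACG00000007833 at 21.5 ± 21.2 against 13.1 ± 11.4 CPM (log2 fold change 0.63, SE 0.14, adjusted p = 0.012). DESeq2 did not call ENSGACG00000017329 (adjusted p = 0.18), and limma-voom did not call ENSGACG00000005997 (adjusted p = 0.17) or ENSGACG00000007833 (adjusted p = 0.070). In all, 7 genes were higher on the right and 5 on the left by edgeR's test. Among 21 splits of the fish, the real one included, the highest other split gave 11 calls against the real 12. No gene was called within any single plate (edgeR, 0 in each, with 576, 342 and 450 at an unadjusted p under 0.05), and the 12 genes kept their direction in each plate, though they were chosen over these same fish. Without the family block 7 genes were called.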

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

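The tests of plate and sex label for genes higher in females, of gene copies, of other tissue and of care on the gene group were chosen only after the result was seen.

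Among 40 sets of values of the 8 families of a rearing group, 4 held a family far from the others, where chance gives about 2. The total count of family 11 (hand-reared) was 18857269, with the next hand-reared family at 16209713, and it had 18 fish. In father-reared family 27, ENSGACG00000016157 rose by 228.7 CPM from baseline to open field, with the next father-reared family at 147.9 CPM. The remaining 2 values are scores of gene groups, sets of genes whose values rise and fall together among siblings after sex, plate, hemisphere and exposure are removed. Father-reared family 31 scored 1.74 in gene group 1, with the next father-reared family at 0.18, and 0.64 in gene group 3, with the next father-reared family at -0.46.

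With single fish as independent replicates, 817 genes differed between rearing groups. A candidate explanation is that siblings deviate together whatever their care: 8 of 21 splits of the same families into 8 and 8, the real one included, gave at least as many genes, and the highest other split gave 1456. The count of 817 is thus what family structure alone can give. It does not exclude that some of these genes depend on care.

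Many genes called higher in females lay near -1 on the log2 scale, where males have 1 count for every 2 in females. Over the genes between -1.1 and -0.9 the median was -0.98, -0.99 and -0.98 in the 3 plates fitted alone, the value nearest to 0 being -0.977, but these genes were chosen over the same fish. Genes chosen in this range in 1 plate had medians between -0.98 and -0.96 in the other plates, which hold other fish, so the range was not particular to 1 plate. Plate was also a term of the main fit. In ENSGACG00000006281, 0 fish with usable depth lay on the other sex's side. Wrong sex labels would draw fold changes towards 0 and could not by themselves place genes near -1. Neither check therefore lends weight to the explanation that follows. The pattern may reflect 1 copy of these genes in males against 2 in females. With no chromosome map for these identifiers, the 33.6% of female-higher calls in this range cannot be placed on a sex chromosome, and this explanation stays open.

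Gene group 1 (1.84% of the tested genes) scored -0.08 ± 0.85 in father-reared families (SD, n = 8) and -0.78 ± 0.12 in hand-reared families (SD, n = 8), a difference of 0.70 (exact permutation test, two-sided, p = 0.014, and 0.138 adjusted over 13 gene groups). The father-reared families were not all higher. Families 20, 26, 31 and 35 scored 0.16, 0.06, 1.74 and 0.18. Families 07, 17, 19 and 27 scored -0.49, -0.81, -0.80 and -0.72, in or beside the hand-reared range of -0.94 to -0.57. Depth, sex ratio and family 31 did not carry the whole of the observed difference. With depth as a term it was 0.696, and in the lower sex it was 0.607. Without family 31 it was 0.434 (exact permutation p = 0.0202, 15 families, not adjusted over the 13 gene groups). Sex was already a term of the score, and both sexes came from the same families. These values therefore do not decide whether the difference exceeds chance. The lowest difference in a single plate was 0.488 (exact permutation p = 0.193 there). Each plate held fish of all 16 families and plate was a term of the score. Single plates thus measured the same families again and decide little about plate. Family accounted for 62.9% of the variance of the score. Tissue other than brain in some dissections may still contribute, since without gene names no marker could be looked up, and shared parents were not known. Paternal care stays open, with an adjusted p of 0.138.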

How the results depend on the processing

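The fits of single plates for sex, hemisphere and rearing and the comparison of the responses of families with its 3 alternatives were chosen after seeing the data.

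No fold change of a named gene changed sign. Sex calls were mostly higher in males over all fish, and 66.5%, 52.1% and 70.21% of the calls made in single plates were higher in females, while 1028 of the 1049 genes called over all fish kept their direction in each plate. The 2 leading genes that rose in the open field and the 4 named for sex kept direction and call in every alternative run: ENSGACG00000010476 ranged from 1.40 to 1.58 and ENSGACG00000016157 from 1.06 to 1.29. ENSGACG00000003306 ranged from 3.94 by limma-voom to 5.67. ENSGACG00000010806 kept its call in 8 of 15 alternatives and ENSGACG00000011606 in 6 of 15, both always lower in open-field fish. The hemisphere genes lost their call in 3 to 5 of 9 alternatives each, and ENSGACG00000005997 fell to 0.04 in plate 2, while ENSGACG00000006256 stayed between -1.40 and -1.15 and ENSGACG00000017329 between -1.93 and -1.26.

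With part of the fish, exposure gave 31 calls in left and 24 in right sides, 35 in females and 21 in males, and 24, 22 and 21 in single plates, and the cause of the differences was not tested. Sex gave 391, 507 and 339 and hemisphere 0, 0 and 0 in single plates (edgeR, with 576, 342 and 450 at an unadjusted p under 0.05). Hemisphere without the family block gave 7, and the cause was not tested.

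Rearing by family sums gave 0% of the tested genes, against 0.260% by DESeq2 (20 genes), 2.54% by limma with family as a random effect and 10.6% with fish as the unit (817 genes). At baseline these were 0.338%, 1.16% and 4.79%, and after the open field 0.169%, 1.07% and 4.27%. Fish as the unit treats siblings as independent, and limma took a single sibling correlation for all genes. Over all fish, other splits of the families gave up to 20 genes by DESeq2 and up to 3.40% of genes by limma. For DESeq2 and limma the cause of the higher counts was not tested. Leaving out each family in turn gave 0% to 0.0130% over all fish (1 gene without family 26) and the same range at baseline (1 gene without family 39). Family sums within single plates gave 0, 0 and 0 (edgeR, with 595, 509 and 338 at an unadjusted p under 0.05).

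Without the filter on low counts, rearing by exposure, sex by rearing and sex by exposure each gave 1 gene in place of 0, and 3 genes fell in hand-reared fish in place of 0; 20626 genes were then tested. The response difference between rearing groups was 0.066, 0.068 and 0.128 log2 units in its alternatives, the last with the shallow library of fish 25E6, where the lowest family stood at -0.079.

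Fish that share a family and a number did not pair by their counts: after family and the other terms were removed, 9 such pairs (7.89%) correlated above 0.1. With this number as a block, exposure gave 50 genes, 44 of them among the 48, hand-reared fish 25, father-reared fish 30 and rearing by exposure 0 (edgeR, 268 at an unadjusted p under 0.05).

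The gene list tests, with an estimated correlation or with the sibling block, were not run for want of gene symbols. Depth limits the tests to 7682 of 20626 genes.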

Other observations

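The splits at baseline and after the open field by DESeq2 and limma, the comparison of the responses of families and the share of variance due to care were chosen only after the result was seen.

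Gene group 1 also followed sex. Its score was higher in males in 16 of 16 families, by 0.38 ± 0.20 (SD, n = 16; exact sign-flip test, two-sided, p = 3.1e-05, the smallest these families can give, and 4.0e-04 adjusted over 13 gene groups). Of its genes 88.7% were called higher in males. It did not follow exposure, with a mean difference of 0.03 ± 0.23 (exact sign-flip p = 0.62).

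Fish-level labels were reassigned within the design to see how many genes other splits call. For exposure, 1 of 21 splits reached the real 48 genes (highest other 6), in hand-reared fish 1 of 21 reached 25 (highest other 1), and in father-reared fish 1 of 21 reached 30 (highest other 4). For sex, 1 of 21 reached 1049 (highest other 1). No other split drawn came near these counts. A share of 1 of 21 is the smallest that 21 splits can give, and it was not adjusted over the tests of this kind. For hemisphere, 1 of 21 splits reached 12, and the highest other gave 11, so the margin was 1 gene.

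Chance could not be excluded for rearing by edgeR. At an unadjusted p under 0.05, 19 of 100 splits of the families reached the real 549 genes (highest other 914), 19 of 100 reached 515 at baseline (highest other 769), 33 of 100 reached 461 after the open field (highest other 803) and 97 of 100 reached the 3.02% of genes for rearing by exposure (highest other 10.2%). For sex by rearing 19 of 21 reached 327 (highest other 607), and for sex by exposure 8 of 21 reached 387 (highest other 636).

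At baseline the other tools gave more rearing genes than any other split drawn: DESeq2 called 26 (1 of 21 splits, highest other 12) and limma with family as a random effect 89 (1 of 21, highest other 63). A share of 1 of 21 is the smallest that 21 splits can give. It was not adjusted over the tests of this kind, and 19 of 100 splits reached edgeR's 515 genes. The counts at baseline are therefore weak evidence against chance. Chance was not excluded over all fish, with 20 by DESeq2 (2 of 21, highest other 20) and 2.54% of genes by limma (2 of 21, highest other 3.40%), nor after the open field, with 13 by DESeq2 (2 of 21, highest other 13) and 1.07% of genes by limma (2 of 21, highest other 1.38%). Gene group 1 held 24 of the 26 and 67 of the 89 genes at baseline, so these counts largely describe a single group of genes and are not independent of it. That group's own rearing difference had an exact permutation p of 0.138 adjusted over 13 gene groups. Family 31 stood far from the other father-reared families in it, and neither DESeq2 nor limma was refitted without that family.

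A hypothesis that rearing changes the size of the response to the open field was tested on the mean response of each family, and the exact permutation p was 0.123. A hypothesis that rearing accounts for more of the variance between families than other splits was tested on family means over all tested genes. Rearing accounted for 9.60%, the median split for 6.50%, and 325 of 6435 splits gave as much (exact p = 0.0505). For the open-field minus baseline differences of families it accounted for 5.58%, and 6177 of 6435 splits gave as much (exact p = 0.96). None of these decides for or against an effect of rearing.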
